A study of Drosophila melanogaster with 4 samples.

How the data were processed

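The data are lists of H4K8ac-enriched clusters from ChIP-seq of Oregon-R larvae at the third instar, with 1 list for each of 2 ChIP replicates and 1 list for the whole series. The 2 groups were taken from the titles of the samples, H4K8ac ChIP (2 samples) and input DNA (2 samples). The antibody was a rabbit polyclonal raised against a peptide of human histone H4 acetylated at lysine 8, per the labels. Chromatin was crosslinked with formaldehyde and sonicated before the precipitation, per the labels' protocols. Nothing in the labels says whether the replicates came from separate collections of larvae, so the spread between them may be technical.

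Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The lists use FlyBase release 5 coordinates, per the file headers. The cluster caller, its thresholds, the way the inputs were used and the reads behind the series-wide list are not given in the sources used here. The authors deposited for each cluster an arm, a first and a last base, and a score whose scale and reference are not given in the sources used here. The score was therefore used to rank and filter clusters within a list and is printed as the authors' value. The exception is a comparison of scores between lists among the additional observations, where its limit is stated. The shortest cluster was 1301 bp in both replicate lists and shorter in the series-wide list, as found from the values, so the replicate and series-wide lists did not share a length minimum. No list gives read counts, so the depth per sample is unknown and intervals for counting error could not be made. Lengths of the 14 sequences were taken from the file headers. There were 0 columns of samples outside the series.

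Cluster sets were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the main counts of shared clusters were checked with bedtools 2.31.1 and came out identical. A cluster counted as shared when it had at least 1 base in the other list. Chance overlap was measured with 1000 circular shifts of replicate 1, in which all clusters of an arm moved by one random distance and wrapped round its end. Lengths and spacing of the clusters were thereby kept. The p-value is one-sided and cannot fall below 0.001. The shift test was tested on simulated lists made from the replicate 1 cluster lengths, with 10 draws for each planted share of shared clusters and 99 shifts per draw. The simulated clusters were placed at random along each arm, so the clumping of the real lists was not simulated. With 0% planted, 0 of 10 draws fell under 0.05, which is too few draws to measure a rate of false positives. With 50% and 80% planted, 10 of 10 draws did each time, and the share found was within 0.91 and 0.52 percentage points of that planted plus chance. The expected share counts an unplanted cluster as able to meet only the unplanted part of the other list, a correction made after the first run of the simulation. Scores were compared with a Spearman correlation over clusters paired one to one by largest overlap. The covered share of an arm is the number of bases in clusters divided by the arm length in the header, and the X ratio divides the X share by the mean share of 2L, 2R, 3L and 3R. With 1 antibody group and 2 replicates, no test between groups of samples could be made, and means are given with the SD of 2 replicates.

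The regions named in the text follow a rule set before the data were examined. It takes the 10 longest and the 5 highest-scoring clusters of the series-wide list, and the 5 longest stretches of the major arms with no cluster in either replicate. Other regions are named as extremes of a replicate list or of 1 Mb windows. Comparisons of genes, promoters and gene lists had been planned and were not run, because the gene table used here follows release 6 and the clusters follow release 5, and coordinates of one release cannot be read on the other. No gene is therefore named from a position. Alternatives set before the data were examined were a stricter score threshold (clusters at or above the median score), stricter overlap rules, merging of clusters closer than 1000 bp, leaving out clusters under 500 bp, arm spans in place of arm lengths, each replicate alone and the series-wide list. Alternatives chosen after seeing the data were shifts of 20 to 200 kb, the higher-scoring clusters of one replicate against all of the other, arms without the 2 Mb nearest the centromere, and series-wide clusters of at least 1301 bp.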

Results

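The acetylation of histone H4 at lysine 8 (H4K8ac), a histone mark found in open and transcribed chromatin, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in larvae of the wild-type Drosophila melanogaster strain Oregon-R. The larvae were at the third instar, the last larval stage before the animal forms a puparium. The series held 4 libraries, made up of 2 H4K8ac ChIP replicates and 2 input DNA libraries. Enriched stretches of the genome, called clusters here, were analysed for each ChIP replicate and for 1 list of the whole series. No file of an input library was analysed here, and how the inputs entered the authors' calls is not given in the sources used here. The lists gave no read counts, so the depth behind each cluster is unknown and no counting interval can be attached to a cluster. The design holds 1 antibody, 1 stage and 1 strain, and the comparisons it allows are between the replicates, between the replicate lists and the series-wide list, and between parts of the genome.

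H4K8ac clusters covered a minor part of the major chromosome arms in each replicate, with a few very long domains among many short clusters. Replicate 1 held 5692 clusters over 17.6 Mb and replicate 2 held 5482 clusters over 16.3 Mb. This corresponds to 14.2% ± 0.79 (SD, n = 2) of arms 2L, 2R, 3L, 3R and X. The median cluster was 1987 bp long in replicate 1 and 1986 bp in replicate 2, and the shortest was 1301 bp in both. Clusters of 10 kb or more numbered 201 in replicate 1 and 168 in replicate 2. They made up 3.53% and 3.06% of the clusters but 20.1% and 17.9% of the cluster bases. The longest cluster was at the same place in both replicates, at 2R 6929937 to 6993015 (63.1 kb) in replicate 1 and 2R 6929877 to 6993161 (63.3 kb) in replicate 2. Longer clusters had higher scores, with a Spearman correlation across clusters of 0.61 in replicate 1 and 0.56 in replicate 2. Clusters of one genome are not independent replicates, so no p-value is attached to these correlations.

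The replicates marked the same places more often than chance, and the longest clusters of each were found in the other. Of the replicate 1 clusters, 3904 (68.6%) shared at least 1 base with a replicate 2 cluster, and 4024 of the replicate 2 clusters (73.4%) shared a base with replicate 1. Circular shifts of replicate 1 along each arm gave 22.7% ± 1.04 and 23.8% ± 1.10 (SD over 1000 shifts). The lists had 11.8 Mb in common, or 67.0% of the replicate 1 bases and 72.5% of the replicate 2 bases. The Jaccard index of covered bases was 0.53, against 0.079 ± 0.0061 over the shifts. None of the 1000 shifts reached any of these 3 observed values (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). When a shared cluster had to match a single cluster over at least 50% of both, the shares were 44.2% and 45.9%, against 5.83% and 6.05% over the shifts (permutation p = 0.001).

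All 201 clusters of 10 kb or more in replicate 1 and all 168 in replicate 2 met a cluster of the other replicate. The circular shifts gave 43.3% ± 4.28 and 44.8% ± 4.41 for these long clusters (SD over 1000 shifts), and at most 61.2% and 65.5%. In the quartile of longest clusters, 97.5% of replicate 1 and 97.4% of replicate 2 were shared, against 29.8% and 30.8% over the shifts. In the quartile of shortest clusters the shares were 43.7% and 48.9%, against 19.1% and 20.2%. By score, the share found in the other replicate ran from 52.7% in the lowest quartile to 87.8% in the highest in replicate 1, and from 64.4% to 84.5% in replicate 2. The shifts gave 20.5% to 26.6% and 21.7% to 27.2% for these quartiles. The split by length and score was made after the data were seen. Clusters found in 1 replicate alone had a median length of 1585 bp in replicate 1 and 1545 bp in replicate 2, against 2341 bp and 2204 bp for shared clusters.

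**Figure D1:**
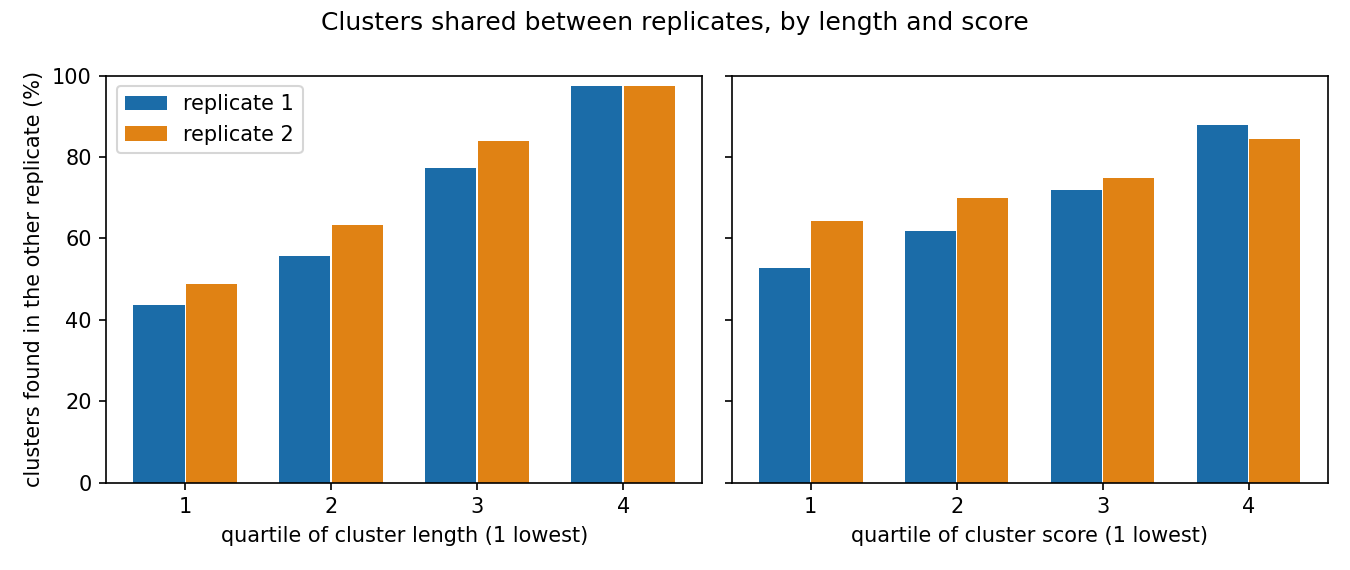
Share of clusters (%) of each replicate that met a cluster of the other replicate by at least 1 base, by quartile of cluster length (left) and of the authors' score (right), with 1 bar per replicate. The shares rise from 43.7% and 48.9% in the shortest quartile to 97.5% and 97.4% in the longest.

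Cluster scores, which were the authors' own, ranked shared regions alike to a moderate degree. Over the 3400 pairs of clusters that were each other's largest overlap, the Spearman correlation across clusters was 0.57 for the score and 0.60 for the length. Longer clusters had higher scores within each list, so part of the score agreement may follow from length. No comparison at equal length was made.

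The series-wide list was larger than either replicate list and contained nearly all of both. It held 9912 clusters over 33995177 bp, 2.00 times the mean of the replicates, and its shortest clusters were shorter than any in the replicate lists. Of the replicate clusters, 99.6% of replicate 1 and 99.4% of replicate 2 met a series-wide cluster. Of the series-wide clusters, 2499 (25.2%) met clusters of both replicates, 1342 (13.5%) of replicate 1 alone, 1079 (10.9%) of replicate 2 alone and 4992 (50.4%) of neither. When at least 50% of a series-wide cluster had to be covered, 1592 (16.1%) were in both and 5588 (56.4%) in neither. Under the rule of 1 base, the clusters in both had a median length of 5637 bp and together spanned 20.8 Mb, whereas those in neither had a median of 1297 bp and spanned 7.35 Mb. By bases, 34.7% of the series-wide list lay in both replicate lists and 35.7% in neither. Whether the series-wide list was called on pooled reads is not given in the sources used here, so it was not treated as a further replicate.

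Among the 5 major chromosome arms, clusters covered the largest shares of 3L and 2R and the smallest of the X. Clusters covered 17.4% ± 0.78 of 3L, 16.8% ± 0.99 of 2R, 13.9% ± 0.80 of 3R, 13.2% ± 0.79 of 2L and 9.77% ± 0.62 of the X (SD, n = 2 for each). The X lay below every one of the 4 autosomal arms in both replicates, at 10.2% in replicate 1 and 9.33% in replicate 2, while the lowest autosomal value was 13.7% and 12.6% on 2L. The ratio of the X share to the autosomal mean was 0.641 in replicate 1 and 0.632 in replicate 2, and 0.776 in the series-wide list. With 2 replicates no test across arms was run. The replicate 1 value on the X was below the replicate 2 value on every autosomal arm, so the difference exceeded that between replicates. In the replicate lists the X had both fewer and shorter clusters. It carried 39.9 clusters per Mb in replicate 1 and 36.5 in replicate 2, against autosomal means of 49.8 and 48.3, and its mean cluster length was 2558 bp and 2554 bp against 3191 bp and 3042 bp. In the series-wide list the X was close to the lowest autosomal arm in number, with 79.3 clusters per Mb against 79.7 on 2L and an autosomal mean of 84.0, while its mean cluster length was 2919 bp against 3550.5 bp. The median cluster length of the X in that list was 1779 bp, against 1775 bp on 2L and 1816 to 1825 bp on the other autosomal major arms. Clusters of 10 kb or more made up 2.01% and 2.08% of the X clusters in replicates 1 and 2, compared with 3.28% to 4.25% and 2.80% to 3.70% on the 4 autosomal arms. The X clusters nonetheless had the highest median scores of the major arms, at 0.661 in replicate 1 and 0.688 in replicate 2. The highest autosomal medians were 0.601 and 0.629, on 2R. Covered share counts called clusters, so a lower share does not by itself mean a weaker mark.

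**Figure D2:**
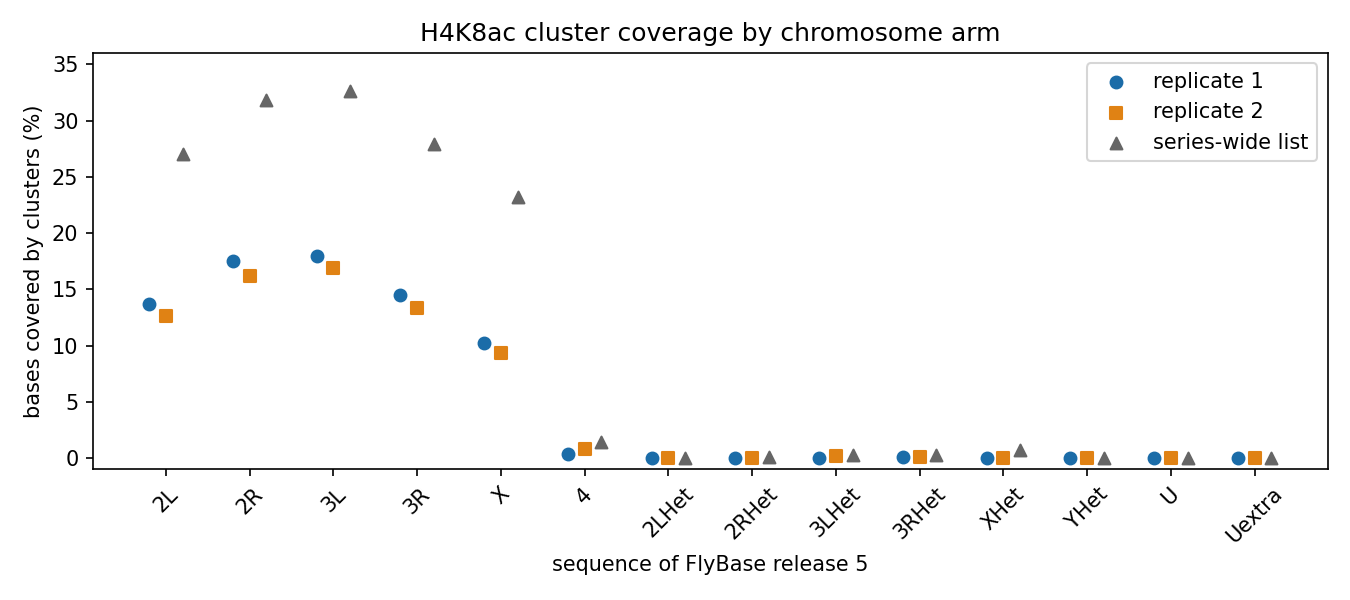
Share of bases (%) covered by H4K8ac clusters on each sequence of FlyBase release 5, with 1 point each for replicate 1, replicate 2 and the series-wide list. The X lies below the 4 other major arms in all 3 lists, and chromosome 4 and the heterochromatic and unplaced sequences lie close to 0.

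Chromosome 4 and the heterochromatic scaffolds were almost free of clusters. Chromosome 4, the small and largely heterochromatic autosome of the fly, held 3 clusters in replicate 1 and 6 in replicate 2, covering 0.319% and 0.782% of its 1351857 bp. All 3 replicate 1 clusters lay between 539834 and 546838 on chromosome 4, where replicate 2 also had 3 clusters. The 8 heterochromatic and unplaced sequences (2LHet, 2RHet, 3LHet, 3RHet, XHet, YHet, U and Uextra) make up 48.3 Mb. They held 1 cluster in replicate 1 and 4 in replicate 2, and no cluster in either replicate was called on 2LHet, XHet, YHet, U or Uextra. The single scaffold cluster common to both replicates was on 3RHet, at 2469904 to 2472631 in replicate 1 and 2470979 to 2472346 in replicate 2. No mappability measure was used here, so the share of these sequences that reads could reach is unknown.

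Along the major arms, coverage varied over Mb-long stretches in the same way in both replicates. Over the 117 full windows of 1 Mb, the Spearman correlation across windows between the replicates was 0.98. The 3 most densely covered windows were the first Mb of 3L (37.6% in replicate 1 and 36.2% in replicate 2), 10 to 11 Mb on 3L (33.6% and 32.6%) and 14 to 15 Mb on 2L (33.0% and 30.1%). The lowest were 23 to 24 Mb on 3L, with no cluster in either replicate, then 22 to 23 Mb on 2L (0.37% and 0.52%) and the first Mb of 2R (0.59% and 0.38%). These 3 windows lie at the centromere-proximal ends of their arms in the standard orientation. In the 2 Mb nearest the centromere, the covered share was 4.35% and 4.52% on 2L, 2.80% and 1.73% on 2R, 3.29% and 2.80% on 3L and 2.10% and 2.08% on the X for replicates 1 and 2. On 3R the same stretch was covered over 16.8% and 16.0%, above the rest of that arm at 14.3% and 13.2%. The 2 Mb were counted from the end of each arm sequence. How much heterochromatin they hold on each arm was not measured here, so the arms may not be alike in this stretch. The windows and the 2 Mb stretch were chosen after the values were seen.

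**Figure D3:**
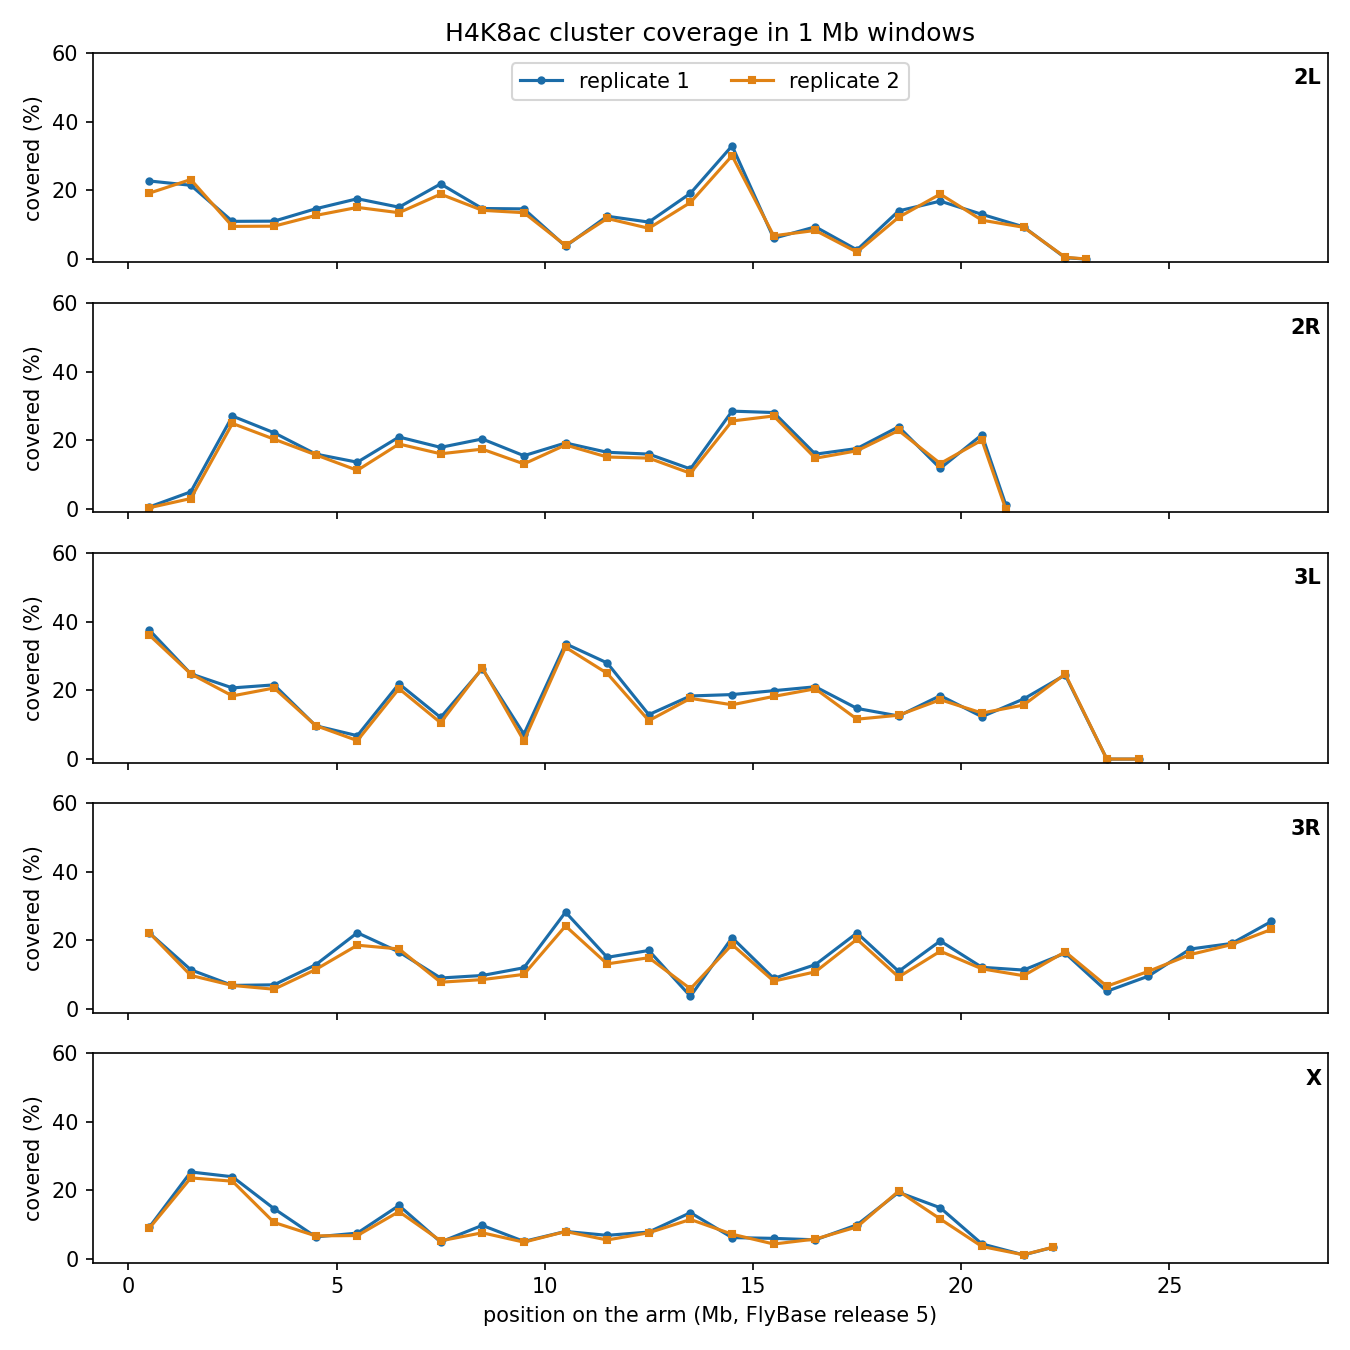
Share of bases (%) covered by H4K8ac clusters in windows of 1 Mb along the 5 major arms (position in Mb, FlyBase release 5), with 1 line per replicate and a shorter window at the end of each arm. Coverage peaks at 37.6% and 36.2% in the first Mb of 3L and falls to 0 near 23 Mb on that arm, and the lines of the replicates run close together.

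The 10 longest clusters of the series-wide list were 76.6 to 117.1 kb long, and both replicate lists covered most of each. The longest ran from 10733412 to 10850478 on 3L, and 80.2% of its bases were in replicate 1 and 78.4% in replicate 2. It was split into 13 clusters in replicate 1 and 16 in replicate 2. The next was 96.5 kb long, from 11324992 to 11421540 on 3L, and was covered over 98.7% and 97.5%. Next came 88987 bp on 2L from 1385456 to 1474442 (89.5% and 90.7%), 88.2 kb on 3R from 10219064 to 10307280 (98.8% and 93.4%) and 84.4 kb on 3L from 8797540 to 8881964 (89.8% and 93.0%). On 2R lay 4 more regions of 76.6 to 81.5 kb, at 16004452 to 16085902, 6912934 to 6993474, 2389306 to 2467632 and 14167562 to 14244132. The remaining region, of 77.9 kb on 3L from 748964 to 826904, had the highest score of the 10, at 1.01, and was covered over 99.2% and 96.8%. None of these 10 domains was on the X. The X held 63 of the 564 series-wide clusters of 10 kb or more, so its absence among 10 domains says little.

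**Figure D4:**
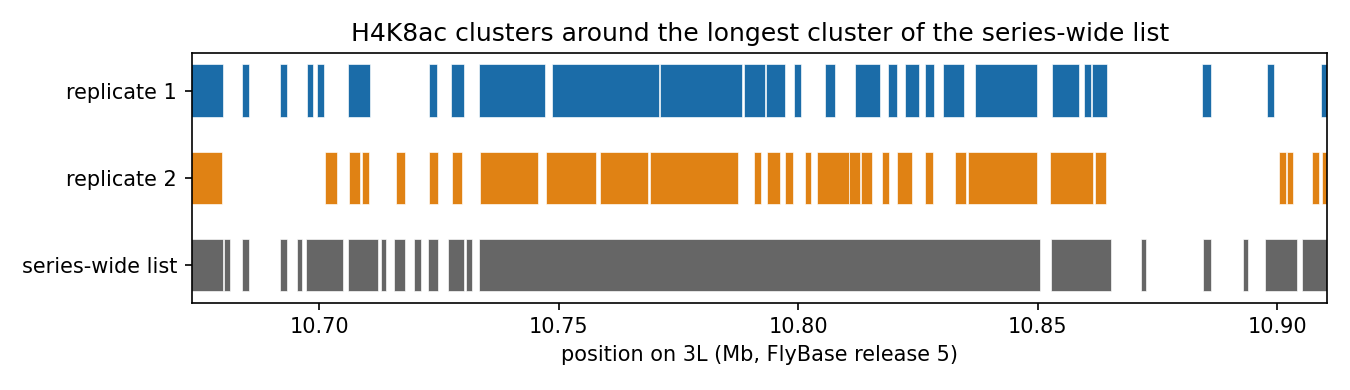
H4K8ac clusters of replicate 1, replicate 2 and the series-wide list around the longest series-wide cluster on 3L (position in Mb, FlyBase release 5). Each bar is 1 cluster drawn to scale, and the 117.1 kb series-wide cluster is divided into 13 clusters in replicate 1 and 16 in replicate 2.

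The 5 series-wide clusters with the highest scores were short and were in neither replicate list. The longest of them was 1115 bp, shorter than the shortest replicate cluster. They lay on U at 7456766 to 7457766 (score 2.48), X at 14451750 to 14452864 (2.07), 3R at 8745852 to 8746852 (1.90), chromosome 4 at 97220 to 98220 (1.85) and 3RHet at 1795038 to 1796044 (1.77). In each replicate list the cluster with the highest score was shared. It lay at 3R 878072 to 894668 in replicate 1 and at X 1454284 to 1462514 in replicate 2. The 3R region was called in all 3 lists with nearly equal borders, and had the second highest score of replicate 2. A replicate list also held a short cluster with a high score that was not shared. At X 19823009 to 19824360 (1352 bp, score 1.17), the third highest of replicate 1 met no cluster of replicate 2.

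The 5 longest stretches of the major arms without a cluster in either replicate were 411 to 1600 kb long. The longest was the last 1600 kb of 3L, from 22943213 to 24543557. The others were 597 kb on 2R from 19180 to 616656, 588 kb on 2L from 22147064 to 22734992, 587 kb on 2R from 979606 to 1566606 and 411 kb on 3L from 13495253 to 13906411. The series-wide list covered 0.011% to 1.43% of these stretches. The last one was the only stretch of the 5 away from the centromere-proximal end of its arm.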

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

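The shifts of 20 to 200 kb, the higher-scoring clusters against a complete list, the arms without the 2 Mb nearest the centromere and the series-wide clusters of at least 1301 bp were tests chosen after the results were seen. The overlap of the replicates stayed above the shifts at a permutation p of 0.001 under every alternative run, from 44.2% of replicate 1 clusters with reciprocal 50% overlap to 79.9% when its higher-scoring clusters were set against all of replicate 2. With the planned stricter score threshold on both lists the shares fell to 61.2% and 65.0%, against 16.0% and 16.8% over the shifts. Leaving out clusters under 500 bp removed none and tested nothing. The shifts of 20 to 200 kb raised the chance share to 27.3% and 28.8%. With only clusters at or above the median score, each replicate covered 11.7 Mb on average and the X to autosome ratio was 0.772, against 0.637 ± 0.0058 for the full lists (SD, n = 2). That ratio was 0.623 over the span of the clusters, 0.776 in the series-wide list, 0.649 without the 2 Mb nearest the centromere, and 0.632 to 0.641 when either replicate was left out. The X stayed below the autosomal mean in all of these. Under the rule of 50% coverage, 16.1% of series-wide clusters were in both replicate lists and 56.4% in neither. Among series-wide clusters of at least 1301 bp, 34.4% were in both and 34.2% in neither. The score correlation was 0.628 over reciprocal 50% pairs. Some of these changes follow from the rules. Leaving out clusters under the median score can only lower the covered bases. Requiring 50% coverage can only lower the share in both lists and raise that in neither. The clusters in both numbered 2499 with and without the length limit, so their share rose as the total fell from 9912 to 7275. One score limit per list keeps more clusters of an arm with higher scores, and the X had the highest median score of the major arms. The cause of the other changes was not tested. Of the 18 alternative values for chromosome 4 and single arms, 13 moved by more than 1 SD of the replicates. All 6 were lower with clusters at or above the median score and all 6 were higher in the series-wide list, and 3L was higher over the span of the clusters, where the other 5 moved by less. Leaving out either replicate leaves the value of the other and says nothing about stability here. No paired analysis was possible because the inputs, which share replicate numbers with the ChIP samples, had no list analysed here. The planned comparisons of genes and gene models were not run, and overlap cannot be computed with 1 replicate left out.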

Other observations

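The arms differed in how their cluster-free sequence was arranged. Stretches of 200 kb or more with no cluster in either replicate numbered 20 on 2L, 12 on 3R, 9 on 3L, 9 on the X and 6 on 2R. They took up 23.6% of 2L, 15.4% of 3L, 11.7% of 3R, 10.6% of 2R and 10.3% of the X. The X, the least covered major arm, had the smallest share of its length in such stretches, but at this limit of 200 kb it lay only just below 2R. A group of long clusters with high scores lay near the centromere-proximal end of 3R. On the other major arms the 2 Mb nearest the centromere were covered over 1.73% to 4.52% in the replicates. In the series-wide list it included 834596 to 872460 (37.9 kb, score 1.11), 878042 to 894778 (16.7 kb, score 1.25) and 913694 to 952586 (38.9 kb, score 1.04), and each of these was at least 98.8% covered in both replicate lists. These stretches and regions were chosen after their values were seen.

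Below, 3 patterns were weighed, and no biological explanation was tested because the design holds 1 group of ChIP samples. The tests of X scores, centromere-proximal sequence, length minimum, isolation and both score comparisons of the series-wide list were chosen or worded after the result, or values bearing on it, had been seen, and the test of distance to shared bases before.

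The X was covered less than any other major arm. Cluster-poor sequence near the centromere leaves most of the difference, since without those 2 Mb the X to autosome ratio was 0.649. A candidate explanation is a lower number of reads on the X, as in a sample of both sexes where males carry 1 X, because a cluster might then need a higher score to be called. Among clusters of 1301 to 2000 bp the X median score lay above the highest autosomal arm median by at least 0.069 in both replicates, while the 4 autosomal medians spanned 0.011 and 0.010. The labels give no sex and read counts were not used here. Higher scores on fewer clusters cannot tell a lower read number from a true difference in acetylation of the X. The direction of such a difference was not tested, and it stays open.

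Of the 20 series-wide clusters with a score of 1 or more, 10 were in neither replicate list, among them 9 of the 10 highest. All 10 (100%) were shorter than 1301 bp, against 50.2% of all series-wide clusters in neither list, so the longer minimum of the replicate lists is a candidate cause of their absence. Isolated stacks of reads are a candidate source of their height, but distance between clusters does not measure stacking of reads. For the 9 with a neighbour the median distance to the nearest series-wide cluster was 25377 bp, above 100% of 10000 draws of similarly short clusters (median 1683 bp). That median was the distance of the cluster on 3RHet, and the cluster on chromosome 4 lay 312623 bp from its neighbour. Both sequences held few clusters, whereas 99.8% of all series-wide clusters lay on the major arms, so part of the distance may reflect their place. Against isolation as a trait of all these high-scoring clusters, 3 of the 9 had a neighbour within 1 kb. Another 3 of the 10 lay off the major arms, and repeats cannot be separated from single-copy sequence without the reads.

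Series-wide clusters in neither replicate list lay nearer to bases shared by both replicates than under circular shifts. Their median distance to the nearest such base was 15044 bp, against a 95% range of 18687 to 22859 bp over 1000 shifts. This argues against false calls spread evenly over the arms as the source of all of them. It cannot exclude false calls limited to sequence that reads can reach, because no mappability measure was used. The shifts spread clusters over whole arms, and stretches of 200 kb or more without a replicate cluster took up 14.3% of the major arms. Whether the clusters in neither list were called at a lower enrichment stays open. Over all lengths their median score was 0.404, against 0.520 for series-wide clusters in both lists. Median lengths were 1297 bp and 5637 bp, and longer series-wide clusters had higher scores (Spearman correlation across clusters 0.40). At 1301 to 2000 bp the median score in neither list exceeded that in both lists by 0.0027, within its bootstrap standard error of 0.0065. That error was taken over clusters, which are not independent replicates, so it may be too small. That length range held 1947 clusters in neither list but only 91 of the 2499 in both. The bound for that test was widened to 2 standard errors after the result was seen, and under its first wording any value at or above 0 would have counted against a lower enrichment. A comparison between lists was set aside after it was seen. At 1301 to 2000 bp, 67.1% of the series-wide clusters in neither list scored under the lower of the replicates' 5th percentiles for that length. The reason for setting it aside was that 80.2% of the 91 series-wide clusters of that length in both lists did so too. Scores at nearly the same borders also differed by a median of -0.124 and -0.160 (series-wide list minus replicates 1 and 2). For clusters of 5 kb or more these medians were only -0.052 and -0.021.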
